A study of Homo sapiens with 4 samples.

How the data were processed

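The data are gene counts of 4 RNA-seq libraries of HCE-T human corneal epithelial cells, 2 without treatment and 2 treated with cell-free fat extract (CEFFE). Per the labels' protocols, the cells grew in a serum-containing medium with insulin and epidermal growth factor, total RNA was extracted with a kit, and a commercial service made stranded poly-A libraries that were sequenced in paired ends. The titles call the libraries biological replicates. Nothing else in the labels says how separate the cultures were, so the p-values measure the spread between these libraries. Groups and replicate numbers came from the titles, and columns were matched to libraries through the names the labels give. No column was left unmapped.

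The deposited table holds estimated counts per gene, not scaled for depth: 28.0% of the values above 0 are not whole numbers, and the columns sum to different totals. The submitters' processing notes name HISAT2, StringTie, DESeq2 and the build hg19, without versions. Which tool produced the estimated counts, whether counting used strand, and which annotation was used are not given in the sources used here. Antisense and overlapping genes can therefore not be told apart with certainty. The table lists 63241 Ensembl gene identifiers, of which 62666 matched a table of names and 42338 had a gene symbol. Of all identifiers 58174 occur in GENCODE release 29, and some are newer than it. Because the identifiers and the named build do not point to the same annotation, no coordinates are given.

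Estimated counts were rounded to whole numbers for the tests. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with its default filter on low counts (minimum count 10), TMM factors, robust dispersion and Benjamini-Hochberg adjustment over the 15499 genes that passed the filter, two-sided, with no covariate and 2 residual degrees of freedom. CPM values use TMM-scaled library sizes. Log2 CPM values use a prior count of 2. Standard errors of edgeR fold changes are approximate, computed from the fold change and the F statistic. The total per library was 24607807 to 28864395 counts, so that a gene with 0 counts may still be present at up to 0.104 to 0.122 CPM, the level of 3 counts before the TMM factor. Intervals of shares are Wilson 95% intervals. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

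Before the data were examined, 41 gene lists were fixed, 34 for pathways and RNA quality and 7 for cell types, together with the comparisons, the alternatives and the rule for named genes. Of the 41 lists 40 had at least 2 tested members. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with the correlation estimated per list, and with fry, each adjusted over 40 lists. Of all listed symbols 1 matched no identifier. Genes are identified by Ensembl identifier and named by symbol. Named genes were the 10 largest changes in each direction among genes with an adjusted p under 0.05 and a mean of at least 5 CPM whose groups did not overlap, the up to 4 members with the smallest p of each called list, and 13 fixed genes, 1 of which is not reported here. The first part of this rule gave 0 genes, since edgeR called 0. The genes called by DESeq2, the panel of epithelial keratins, and other genes named as examples were chosen after their values were seen.

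Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood method, median-of-ratios, upper-quartile and total-count scaling, no filter on low counts, a filter of 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, and removal of mitochondrially encoded genes. With a library left out, the lone library of its group is assumed to vary like the other group. Alternatives chosen after seeing the data were an offset per library for transcript length and GC, with and without the block, and a block with crossed replicate numbers. The offset came from smooths on transcript length and GC from GENCODE release 29, known for 14847 (95.8%) of the tested genes. A change of sign of a gene that neither fit called, by less than 1 SE, was not counted as a reversal.

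The procedure was tested on simulated data: counts for 15499 genes at the real means and library sizes, with 200 genes changed 1.5-fold (67), 2-fold (67) or 4-fold (66). In the first version genes of the same level had the same dispersion. After its outcome was seen, a version was added with gene-wise dispersions drawn around the trend, which exceed it on average. That version first held 1.5-fold and 2-fold changes only, of which edgeR recovered none, and the 4-fold class was added after that outcome. The share of 2-fold genes recovered depends on how many strong changes are present. In the first, edgeR recovered 46.3%, 97.0% and 100% of the 3 sizes with 5 unchanged genes called, and DESeq2 34.3%, 91.0% and 100% with 3. In the second, edgeR recovered 0%, 35.8% and 90.9% with 4 unchanged genes called, and DESeq2 11.9%, 80.6% and 98.5% with 54. With the replicate block the second version gave 2.99%, 70.1% and 95.5% with 42 unchanged genes called. Median fitted changes were close to those planted (edgeR, second version: 0.99 for 2-fold and 2.04 for 4-fold, on the log2 scale). A planted list of 30 genes raised by 0.4 on the log2 scale gave adjusted p = 1.01e-20 by camera with the preset correlation and 0.172 with an estimated correlation, while 0 of 20 unchanged lists passed with the preset one. Although its members were independent, the planted list was therefore not called with an estimated correlation at this number of libraries. The unchanged lists were independent genes too, so they do not show how often the preset correlation calls lists of correlated genes. In the real data the estimated correlation of the lists called with the preset one ran from 0.09 (G1/S) to 0.98 (ribosomal protein), with 0.38 for hypoxia.

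For the closing section a second hypoxia list (36 genes) and a second interferon list (45 genes) that share no gene with the first lists were compared with 10000 random lists matched on expression and transcript length. FOSL2, TXNIP, VLDLR and CCNG2 were dropped from the second hypoxia list before its test, for no reason recorded, and the test is also given with them. For CEFFE 1, the share of its distance removed by the length and GC correction replaced a rank correlation as the deciding value after the result was seen, and the test of GC as a part was added then. That test was later tightened to ask for a GC trend absent among the other 3 libraries.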

Results

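Poly-A RNA was sequenced from HCE-T cells, an established line of human corneal epithelial cells, kept without treatment or given cell-free fat extract (CEFFE), the liquid that remains when fat tissue is broken up and its cells are removed. The series sets the extract in the context of epithelial repair, nerve damage and inflammation of the cornea, and the 2 groups ask which transcripts differ in treated cells. Each group had 2 libraries, titled as biological replicates. Total counts were 24607807 and 27963544 in controls 1 and 2, and 26822151 and 28864395 in CEFFE 1 and 2. At these depths 1 read corresponded to 0.0346 to 0.0406 CPM, the unit of counts scaled to library size, before the TMM factor that all gene values include. The dose and duration of treatment were not given in the sources used here.

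The cells expressed keratins of simple epithelia, KRT5 and KRT17, and had no detectable KRT3 or KRT12, keratins of the mature corneal surface. In controls KRT8 was at 1970.3 ± 35.3 CPM, KRT18 at 1352 ± 34.4, KRT7 at 1007 ± 55.5, KRT19 at 777 ± 34.1 and KRT5 at 558 ± 13.8 (SD, n = 2). FN1, which encodes fibronectin, stood at 13339 ± 187 CPM. KRT3 and KRT12, the keratin pair of differentiated corneal epithelium, had 0 counts in all 4 libraries, which allows up to 0.122 CPM in the shallowest library before the TMM factor. PAX6, the transcription factor of eye development, had 0 to 2 counts per library, and the basal epithelial factor TP63 had 0 or 1. KRT14, the usual partner of KRT5 in basal cells, had 15 to 17 counts. Of 20 corneal and limbal markers 12 were tested, with a median log2 fold change of 0.03 between CEFFE and control (camera adjusted p = 0.985). The epithelial keratins, FN1 and TP63 and, elsewhere, RN7SK were chosen after their values were seen.

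Genes of hypoxia and glycolysis were higher as a list in CEFFE-treated cells by camera with a preset correlation, but not with an estimated one (adjusted p = 0.922 with an estimated correlation). The directional fry test did not call the list either (adjusted p = 0.36). Of 30 members tested, 29 had a fold change above 0, and the median log2 fold change was 0.32 (SD over genes 0.26). In 28 members both CEFFE libraries lay above both controls, an order that chance gives to 16.7% of genes. Of all tested genes 24.6% had this order. PFKFB4, whose product sets the level of a glycolytic activator, went from 7.02 ± 0.0865 CPM in controls to 16.04 ± 4.74 in CEFFE (SD, n = 2 per group), a log2 fold change of 1.19 ± 0.22 (approximate SE). NDRG1, a classical hypoxia-induced gene, had 54.9 ± 2.27 and 94.6 ± 19.1 CPM (log2 fold change 0.79 ± 0.16). BNIP3, a mitophagy receptor, had 149.7 ± 0.308 and 224 ± 27.8 CPM (0.58 ± 0.12). P4HA1, a subunit of the enzyme that hydroxylates collagen prolines, had 103 ± 6.34 and 144 ± 4.77 CPM (0.48 ± 0.11). Abundant glycolytic enzymes had smaller values, with log2 fold changes of 0.33 for GAPDH, 0.30 for ENO1 and 0.18 for LDHA, and VEGFA stood at 0.28. In CEFFE 2 alone GAPDH and ENO1 were each 0.13 above the control mean and LDHA 0.08. EGLN3 (0.10) and ANKRD37 (−0.43) were the members whose groups overlapped.

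The hypoxia list passed the camera test with a preset inter-gene correlation of 0.01 (adjusted p = 4.4e-16 over 40 lists), and its adjusted p was between 2.8e-27 and 1.69e-10 in 15 alternative settings. By edgeR 8 members passed adjusted over the list alone and 0 over all genes tested, while 13 had an unadjusted p under 0.05; DESeq2 called 2, PFKFB4 and NDRG1. The median difference from the control mean was 0.45 in CEFFE 1, a library that lay apart from the other 3, and 0.22 in CEFFE 2, against 0.05 between the controls. RN7SL2, an RNA without a poly-A tail, had a log2 fold change of 1.24 between the same groups.

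**Figure D1:**
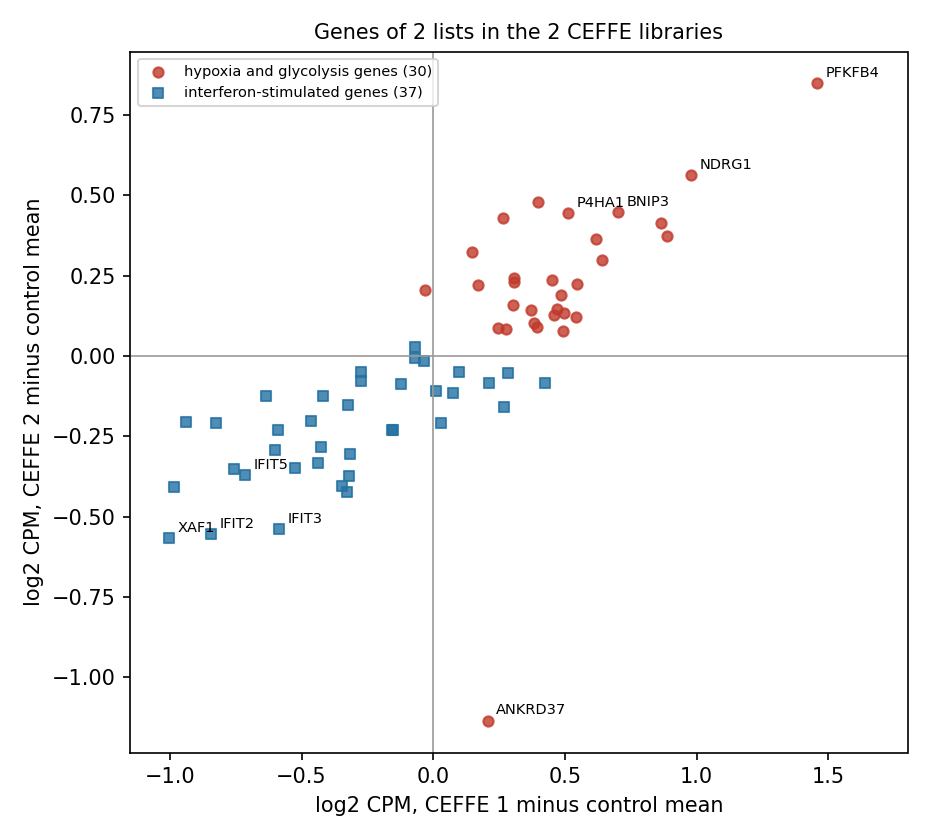
Log2 CPM of CEFFE 1 (horizontal axis) and CEFFE 2 (vertical axis) minus the control mean, with 1 point per gene, for 30 hypoxia and glycolysis genes (circles) and 37 interferon-stimulated genes (squares). PFKFB4 lies farthest to the upper right (1.46 and 0.85) and ANKRD37 at the bottom (−1.13 in CEFFE 2).

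Interferon-stimulated genes were lower as a list by camera with the preset correlation, but not with an estimated one (adjusted p = 0.922 with an estimated correlation). The directional fry test did not call the list either (adjusted p = 0.36). Of 37 members tested 32 had a fold change below 0, and the median log2 fold change was −0.32 (SD over genes 0.24). In 24 both CEFFE libraries lay below both controls, against 16.7% by chance and 23.0% of all tested genes. The IFIT genes, which encode RNA-binding antiviral proteins, had some of the smallest p-values. IFIT2 had 50.8 ± 1.30 CPM in controls and 31.4 ± 4.46 in CEFFE (log2 fold change −0.69 ± 0.14) and IFIT3 had 41.6 ± 1.68 and 28.2 ± 0.644 CPM (−0.56 ± 0.11). IFIT5 had a log2 fold change of −0.53 ± 0.15. XAF1, an interferon-induced antagonist of apoptosis inhibitors, had a log2 fold change of −0.79 ± 0.23. With the length and GC offset IFIT2 was at −0.49, IFIT3 at −0.42, IFIT5 at −0.27 and XAF1 at −0.86. Other members gave values near or above 0, among them ISG15 (0.19), BST2 (0.13), IFI27 (0.07) and RSAD2 (−0.03).

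The interferon list passed camera with the preset correlation (adjusted p = 2.72e-09), with adjusted p between 4.62e-14 and 0.000233 in 15 alternative settings. By edgeR 2 members passed adjusted over the list alone, IFIT2 and IFIT3, and 0 over all genes tested, with 12 at an unadjusted p under 0.05; DESeq2 called 0. The median became −0.21 without CEFFE 1 and −0.20 without control 2, and the list passed camera with the preset correlation in both fits, while RN7SL2, without a poly-A tail, stood at 1.24 between the same groups.

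Metallothionein and histone lists had medians above 0. Of the 5 tested members of the metallothionein list, 4 were metal-binding metallothioneins and all 4 were higher. MT2A had 404 ± 29.7 CPM in controls and 585 ± 121 in CEFFE (log2 fold change 0.54 ± 0.16) and MT1X had a log2 fold change of 0.80 ± 0.25. MT1E (0.63 ± 0.21) and MT1F (0.53 ± 0.17) had values of similar size. SLC30A1, a zinc exporter in the same list, went the other way (−0.35 ± 0.14), and RN7SL2, without a poly-A tail, stood at 1.24 between the same groups. By edgeR all 5 members passed adjusted over the list alone and 0 over all genes tested, all 5 had an unadjusted p under 0.05, and DESeq2 called 0. The list median was 0.54, and the list differed by −0.19 between control 2 and control 1, against 0.73 in CEFFE 1 and 0.32 in CEFFE 2. It was 0.31 without CEFFE 1, the library that stood apart, with MT2A at 0.31, MT1X at 0.37, MT1E at 0.31 and MT1F at 0.32 (camera adjusted p = 0.0092, from 1.75e-05 to 0.0497 in 15 alternative settings; adjusted p = 0.922 with an estimated correlation).

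All 17 tested replication-dependent histone genes had a fold change above 0, with a median of 0.50 on the log2 scale. In 13 both CEFFE libraries lay above both controls, against 16.7% by chance and 24.6% of all tested genes. H1-2, a linker histone, had 19.1 ± 1.07 and 27.8 ± 7.85 CPM (0.54 ± 0.20), and H2BC4 had 1.56 ± 0.0132 and 2.63 ± 0.644 CPM (0.74 ± 0.25). These messages end without a poly-A tail, and the list had been included as a check of poly-A selection. Other RNAs without such a tail also had values above 0 in both CEFFE libraries. Their log2 fold changes were 1.20 ± 0.24 for RN7SL1, 1.24 ± 0.19 for RN7SL2 and 0.56 ± 0.22 for RN7SK. Of these edgeR called 0 (all 3 at an unadjusted p under 0.05) and DESeq2 2, RN7SL1 and RN7SL2. RN7SK was at 3.62 and 4.33 CPM in controls 1 and 2, 6.94 in CEFFE 1 and only 4.90 in CEFFE 2. By edgeR 0 members passed adjusted over the list alone or over all genes, 6 had an unadjusted p under 0.05, and DESeq2 called 0. Camera gave adjusted p = 1.6e-05, with 3.03e-06 to 0.0393 in 15 alternative settings, and adjusted p = 0.922 with an estimated correlation. The median was 0.35 without CEFFE 1 and 0.80 without CEFFE 2, and H1-2 stood at 0.22 and H2BC4 at 0.48 without CEFFE 1.

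The list medians of ribosomal protein, respiratory chain and squamous differentiation genes were higher in CEFFE 1 and close to the controls in CEFFE 2. All 32 cytosolic ribosomal protein genes had a fold change above 0 (median 0.26), with RPL13 at 671 ± 49.4 CPM in controls and 885 ± 205 in CEFFE (0.40 ± 0.17). Of 32 nuclear genes of oxidative phosphorylation 31 were above 0 (median 0.18), with CYC1, the gene of cytochrome c1, at 0.38 ± 0.16. Of 17 squamous differentiation genes 13 were above 0 (median 0.31), with TGM2, a transglutaminase, at 41.8 ± 0.591 and 70.7 ± 15.5 CPM (0.76 ± 0.17) and the stress keratin KRT17 at 0.38 ± 0.15. Relative to the control mean, the 3 medians were 0.46, 0.34 and 0.42 in CEFFE 1 but 0.03, 0.01 and 0.05 in CEFFE 2, where TGM2 stood at 0.52 and KRT6A at 0.32. Without CEFFE 1 RPL13 was at 0.14, CYC1 at 0.15 and KRT17 at 0.16.

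With all 4 libraries these 3 lists passed camera with the preset correlation (adjusted p = 8.92e-08, 0.000252 and 0.0224). Their calls were lost without CEFFE 1, at medians of 0.03, 0.01 and 0.05 and adjusted p = 0.103, 0.832 and 0.239 (each the highest of 15 alternative settings, whose lowest were 2.67e-33, 2.32e-13 and 0.00948), and also when correlation was estimated (adjusted p = 0.922 with an estimated correlation for each). Without CEFFE 2 the medians were 0.46, 0.34 and 0.48. By edgeR 0 members of the ribosomal and respiratory lists passed adjusted over the list alone, with 0 and 1 at an unadjusted p under 0.05 and 0 by DESeq2. The squamous list was also not called with the length and GC offset (median 0.21, adjusted p = 0.136, within 0.00948 to 0.239 in 15 alternative settings). Of its members TGM2 passed by edgeR adjusted over the list alone and 0 over all genes tested, 3 had an unadjusted p under 0.05, and DESeq2 called 1, TGM2.

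G1/S and DNA replication genes had 22 of 31 members below 0 and a median log2 fold change of −0.10. In 16 members both CEFFE libraries lay below both controls, against 16.7% by chance and 23.0% of all tested genes. RN7SL2, without a poly-A tail, stood at 1.24 between the same groups. CCNE2 and CCNE1, the cyclins that drive entry into S phase, had log2 fold changes of −0.64 ± 0.24 and −0.37 ± 0.14, and the replication licensing gene CDC6 had −0.21 ± 0.11. The camera adjusted p was 0.0366, within 0.00142 to 0.219 in 15 alternative settings, and adjusted p = 0.922 with an estimated correlation. The call was lost without control 2 (median −0.08, adjusted p = 0.219), without CEFFE 2 (−0.14, 0.0602), with upper-quartile scaling (−0.06, 0.0842), with a filter of 1 CPM (−0.10, 0.0557) and with the replicate number as a block (−0.11, 0.066). The median was −0.07 without CEFFE 1, where CCNE2 stood at −0.30, and CCNE2 was at −1.09 without CEFFE 2. By edgeR 0 members passed adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 called 0. The list of 30 G2/M genes had a median of 0.01 (camera adjusted p = 0.815), and the proliferation marker MKI67 had 421 ± 35.2 and 359 ± 80.9 CPM, with no call by edgeR (adjusted p = 0.601). Its log2 fold change was −0.23, and −0.016 without CEFFE 1, −0.14 without control 1 and −0.48 without CEFFE 2, where edgeR called it (adjusted p from 3.61e-18 to 1 in 15 alternative settings).

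**Figure D2:**
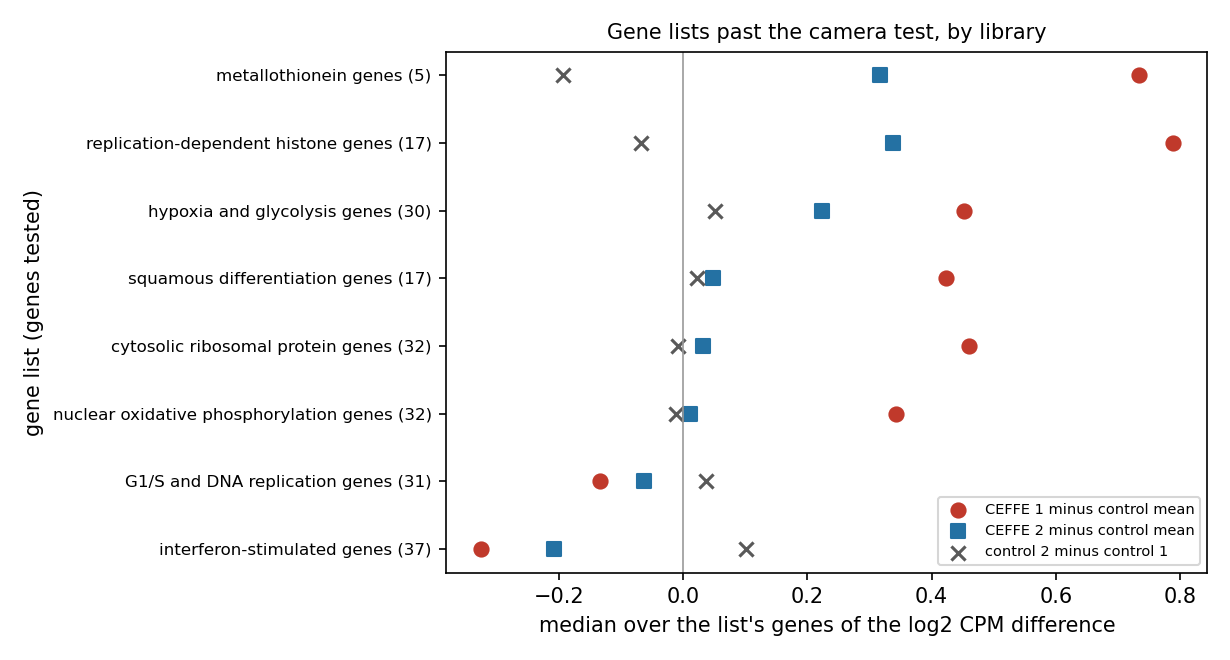
Median over each list's genes of the log2 CPM difference (horizontal axis) for the 8 gene lists past camera with the preset correlation, with the number of genes tested in parentheses; circles are CEFFE 1 and squares CEFFE 2, each minus the control mean, and crosses are control 2 minus control 1. CEFFE 2 lies near 0 for ribosomal protein (0.03), oxidative phosphorylation (0.01) and squamous genes (0.05), and away from 0 for the hypoxia (0.22) and interferon lists (−0.21).

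Inflammatory transcripts, which the title of the series names, showed no shift as a list. The sample titles name no inflammatory stimulus, so an effect of the extract on induced inflammation was not tested. Of 25 cytokine and chemokine genes tested 12 were above 0 and 13 below, with a median of −0.04 (camera adjusted p = 0.967). The test for change in either direction (fry, mixed) passed for this list and for no other of the 40 (adjusted p = 0.0171), with members on both sides. The directional fry test passed for 0 lists, with a smallest adjusted p of 0.36. CXCL2 and CXCL3, which attract neutrophils, had log2 fold changes of 0.65 ± 0.22 and 0.61 ± 0.27, whereas PTGS2, the inducible cyclooxygenase, had −0.54 ± 0.21 and CXCL11 −0.72 ± 0.35. Adjusted over the list alone 0 members passed by edgeR, 2 had an unadjusted p under 0.05, and DESeq2 called 0. IL6 stood at 2.13 ± 0.677 CPM in controls and 1.88 ± 0.212 in CEFFE, IL1B at 1.24 ± 0.00983 and 1.25 ± 0.304, CXCL8 at 11.3 ± 0.0208 and 10.5 ± 0.0303, TNF at 0.729 ± 0.0645 and 0.984 ± 0.0258, and CCL2 at 0.294 ± 0.132 and 0.262 ± 0.175. The edgeR adjusted p was 0.776 for IL6, 0.998 for IL1B, 0.736 for CXCL8, 0.595 for TNF and 0.891 for CCL2. NFKBIA, the feedback inhibitor of NF-kB, had 79.9 ± 2.85 and 80.7 ± 1.27 CPM (0.01 ± 0.11), and its list of 21 tested NF-kB targets had a median of −0.09 (camera adjusted p = 0.15). With the length and GC offset that list was at −0.17 and passed camera with the preset correlation.

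Neurotrophic genes did not pass a test as a list. BDNF, a neurotrophin, had 3.96 ± 0.479 CPM in controls and 3.49 ± 0.248 in CEFFE (edgeR adjusted p = 0.658). The median over 24 neurotrophic and axon guidance genes was −0.06 (camera adjusted p = 0.719).

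Without the length and GC offset the remaining lists gave no call with the preset correlation. With it the p53 (−0.11), YAP and TEAD (−0.17) and immediate early lists (−0.14) passed, and an estimated correlation was not run there. Without the offset, median log2 fold changes among signalling lists were −0.15 for p53 targets, −0.13 for YAP and TEAD targets and −0.12 for immediate early and ERK targets. TGF-beta targets were at 0.03 and angiogenic and growth factor genes at −0.00. Without CEFFE 1 these medians were, in the same order, −0.05, −0.02, −0.12, 0.06 and −0.01. Stress lists had medians of −0.04 for iron handling, −0.05 for NRF2 targets, −0.01 for endoplasmic reticulum stress, 0.04 for heat shock and −0.07 for the amino acid response. Cholesterol synthesis was at 0.03, fatty acid synthesis at −0.08, PPAR targets at 0.08, LXR targets at 0.13 and glucocorticoid receptor targets at −0.05. Without CEFFE 1 the sign changed for fatty acid synthesis (0.01), PPAR targets (−0.02), endoplasmic reticulum stress (0.02) and heat shock (−0.01). The other lists of this group kept their sign, with LXR targets at 0.07 and glucocorticoid receptor targets at −0.02. Immune lists stood at 0.09 for antigen presentation, 0.02 for complement and acute phase genes and −0.04 for inflammasome genes. Barrier lists stood at 0.02 for adhesion and matrix genes, −0.07 for matrix proteases and −0.11 for cell junctions and mucins. Without CEFFE 1 the immune medians were, in the same order, −0.005, −0.04 and −0.09, and the barrier medians 0.09, −0.05 and −0.002. Mitochondrially encoded genes had a median of −0.12. The smallest camera adjusted p among these 32 uncalled lists was 0.0891, for p53 targets, and adjusted over the list alone 1 member each passed in the immediate early (EGR1), TGF-beta (ID1) and amino acid response lists (PPP1R15A). Median, mean and test direction differed in sign in 8 of the 32, those of complement, TGF-beta, G2/M, adhesion, amino acid response, angiogenic, corneal and stromal genes.

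Markers of other cell types were low or gave no call. ADIPOQ, LEP and FABP4, which are abundant in adipocytes, had 0 or 1 count per library, and HBB had 0 in all 4. The 5 tested members of the adipocyte list had a median of 0.23 (camera adjusted p = 0.238), and PNPLA2, LIPE and PPARG among them were present in the control cells at 47.3, 5.01 and 29.8 CPM. Medians were 0.01 over 6 stroma and fibroblast markers, −0.04 over 2 endothelial markers, 0.22 over 2 immune markers and 0.17 over 4 neural, glial and melanocyte markers. Without CEFFE 1 these medians were, in the same order, 0.02, −0.21, 0.09 and 0.04. Of 8 erythroid markers 0 were abundant enough to be tested.

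Gene by gene, the quasi-likelihood test of edgeR called 0 genes higher and 0 lower among 15499 tested at an adjusted p under 0.05. The smallest adjusted p was 0.296. At an unadjusted p under 0.05 there were 1139 genes, 622 higher and 517 lower, where chance gives 775. In 3814 genes (24.6%) both CEFFE libraries lay above both controls and in 3562 (23.0%) below, against 16.7% by chance in each direction. The 2 libraries of a group cannot reach p = 0.05 in an exact permutation test, whose smallest value is 0.333. limma-voom called 0 and DESeq2 called 16 identifiers, 9 higher and 7 lower. The edgeR count rested on which libraries were present: it was 8 higher and 9 lower without control 1, 25 and 8 without control 2, 330 and 289 without CEFFE 1, and 3339 and 3606 without CEFFE 2. On counts simulated for this comparison with gene-wise dispersions, edgeR recovered 35.8% of genes changed 2-fold and DESeq2 80.6%, with 4 and 54 unchanged genes called. These shares rest on the 4-fold changes planted beside them, before whose addition edgeR recovered none of the changed genes. The simulated libraries also varied alike, with no library set apart as CEFFE 1 was. Their gene-wise dispersions exceeded the fitted trend on average, so the shares may not hold for the real libraries.

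The genes called by DESeq2 are listed here after their values were seen, and no theme among them was tested. They were picked from the same 4 libraries, so fits that leave 1 library out are no independent check of them. Of the 16 identifiers edgeR also called 16 without CEFFE 1, 16 without CEFFE 2, 4 without control 1 and 6 without control 2. ID1, a BMP target, had 34.6 ± 1.68 CPM in controls and 16.8 ± 1.84 in CEFFE (DESeq2 log2 fold change −1.05 ± 0.19, adjusted p = 0.000131). EGR1, an immediate early gene, had 9.85 ± 0.910 and 4.51 ± 0.598 CPM (−1.14 ± 0.28, DESeq2 adjusted p = 0.0488). KLF10, a TGF-beta-inducible factor, had 38.2 ± 0.385 and 18.2 ± 6.24 CPM (−1.08 ± 0.23, DESeq2 adjusted p = 0.00697). CUL5 and FAM111B were lower too, with DESeq2 log2 fold changes of −0.92 ± 0.20 and −0.78 ± 0.18. PTGES, the prostaglandin E synthase that acts after PTGS2, was higher at 68.5 ± 2.03 and 109.9 ± 15.9 CPM (0.66 ± 0.16, DESeq2 adjusted p = 0.0408), as was PPP1R15A, a stress-induced phosphatase subunit, at 121 ± 0.533 and 184 ± 14.5 CPM (0.58 ± 0.14, 0.0488). PFKFB4, NDRG1 and TGM2, described with their lists, were called too. In 15 alternative settings the adjusted p of ID1 ran from 5.79e-29 to 0.6, that of EGR1 from 1.53e-12 to 0.677, that of KLF10 from 4.21e-45 to 0.677, that of PTGES from 7.35e-35 to 1 and that of PPP1R15A from 2.26e-29 to 1.

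The other calls of DESeq2 share sequence with near-identical or overlapping genes and are uncertain. VAMP7 is listed under 2 identifiers whose changes were opposite, and their sum was 75.5 ± 1.22 CPM in controls and 68.4 ± 4.41 in CEFFE (log2 ratio −0.14). RN7SL1 and RN7SL2, near-identical genes of the signal recognition particle RNA, had 9.87 ± 2.98 and 22.8 ± 4.98 CPM, and 16.3 ± 4.68 and 38.6 ± 0.229 CPM. Like the histone messages they carry no poly-A tail. H2AC18 (DESeq2 log2 fold change 1.52 ± 0.33, and 1.01 by edgeR without CEFFE 1) has a near-identical neighbour, and BIVM-ERCC5 (−1.96 ± 0.36) is a read-through transcript that overlaps ERCC5.

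CEFFE 1 stood apart from the other 3 libraries. The first principal component held 57.4% of the variance and placed CEFFE 1 at 41.1 and the others between −22.2 and −7.73. Across genes the SD of the log2 CPM difference was 0.46 to 0.53 for pairs with CEFFE 1 and 0.34 to 0.35 for pairs among the other 3. Ribosomal protein genes took 10.5% of counts in CEFFE 1 (Wilson 95% interval 10.5 to 10.5%), 8.14% and 8.02% in controls 1 and 2 (8.13 to 8.15% and 8.01 to 8.03%) and 8.2% in CEFFE 2 (8.19 to 8.21%). The 20 most abundant genes took 9.84% in CEFFE 1 (9.83 to 9.85%) and 8.79 to 9.17% in the others. Mitochondrially encoded transcripts made up 1.05 to 1.24% of counts in all 4. Across genes, the difference of CEFFE 1 from the mean of the other 3 libraries rose with transcript GC (Spearman rho 0.46 over 14847 genes, which are not independent). These intervals cover counting error only.

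**Figure D3:**
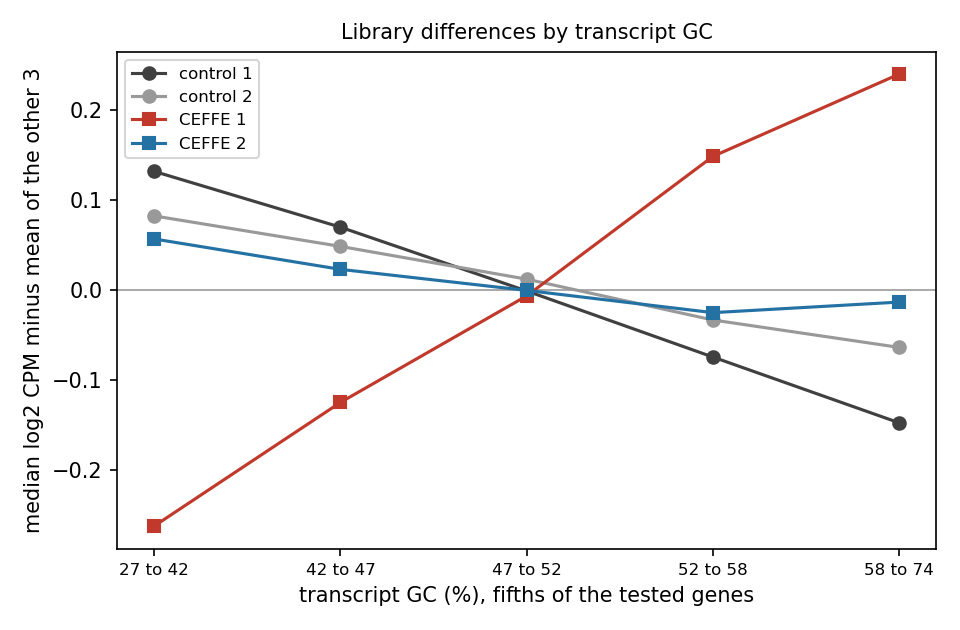
Median log2 CPM of each library minus the mean of the other 3 (vertical axis) in 5 equal groups of tested genes ordered by transcript GC in percent (horizontal axis), with controls as circles and CEFFE libraries as squares. CEFFE 1 runs from −0.26 in the group of lowest GC to 0.24 in the highest, and control 1 from 0.13 to −0.15.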

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

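The length and GC offset, alone or with the replicate block, and the crossed block were chosen after seeing the data, and the other settings before. The edgeR counts of 0 higher and 0 lower stayed at 0 with limma-voom, the legacy method, each scaling, both filters on low counts, removal of mitochondrially encoded genes and the length and GC offset. DESeq2 called 9 higher and 7 lower, of which 5 and 4 changed at least 2-fold. With the replicate number as a block there were 29 higher and 25 lower (21 and 14 at least 2-fold), and with crossed pairs 160 and 280 (51 and 21). Across genes, the difference between controls 1 and 2 and that between CEFFE 1 and 2 had Pearson r −0.14 (Spearman rho −0.26). This gives no ground for pairing libraries by number. It cannot exclude a pairing, since it is 1 correlation and control 1 and CEFFE 1 had opposite GC trends (rho −0.42 and 0.46). The numbers are those of the titles, and the column names carry others (1 and 3 for controls, 2 and 3 for CEFFE). The numbers missing from the column names leave open whether the 2 libraries of each group are all that were made. The block with the length and GC offset gave 42 and 32 (14 and 7 at least 2-fold). Leaving out each library in turn gave 8 to 3339 higher and 8 to 3606 lower, and 8 to 176 and 8 to 223 at least 2-fold, the most without CEFFE 2. The causes of these differences were not tested.

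Among the 8 lists called with the preset correlation, 8 lost the call with an estimated correlation, 3 without CEFFE 1, and 1 each without control 2, without CEFFE 2, with upper-quartile scaling, the 1 CPM filter, the replicate block and the length and GC offset. With that offset 4 further lists passed at the preset correlation, all lower: NF-kB (median −0.17), immediate early (−0.14), YAP and TEAD (−0.17) and p53 targets (−0.11); an estimated correlation was not run with it. Signs changed for IL6, at 0.19 without control 2 (−0.46 to 0.19 with each library left out), and, with the length and GC offset, CXCL8 (0.077) and BDNF (0.047). None of these 3 genes passed in either fit, and the cause was not tested. IL1B (−0.26 to 0.24 over the settings), CCL2 (−1.10 to 0.35) and NFKBIA (−0.085 to 0.057) also changed sign. These changes were by less than 1 SE and were not counted as reversals. The directional fry test, also planned, called 0 lists (smallest adjusted p = 0.36). Depth limits genes of low count, such as CCL2.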

Other observations

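The genes of this paragraph were chosen after their values were seen, and none of them passed edgeR or DESeq2 over all genes with all 4 libraries and no block. With the replicate block edgeR called 1 of the 6, SOCS3, and without CEFFE 1 it called all 6, with ETV4 at 0.51. SOCS3, a feedback inhibitor of cytokine signalling, had 7.23 ± 0.120 CPM in controls and 4.01 ± 0.277 in CEFFE (SD, n = 2 per group), a log2 fold change of −0.85 ± 0.15. JUNB, an AP-1 subunit, had −0.37 ± 0.13 and INHBA, the gene of activin A, −0.46 ± 0.13. ETV4, a transcription factor downstream of ERK, had 9.48 ± 0.0953 and 16.1 ± 3.77 CPM (0.77 ± 0.18), and STC1, a secreted glycoprotein, had 6.36 ± 0.122 and 10.7 ± 0.189 CPM (0.75 ± 0.13). Among mitochondrially encoded genes MT-CO3 had 164 ± 4.73 and 125 ± 15.0 CPM (−0.39 ± 0.12).

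Tests chosen or rewritten after the result was seen were those of depth, of length and GC as the whole cause and of GC as a part for CEFFE 1, those without CEFFE 1 for the hypoxia and interferon lists, and the second lists against each control. CEFFE 1 lay apart from the other 3 libraries. The test of a length and GC trend as the whole cause asked its correction to remove at least 50% of that distance. It removed 9.61% of the SD over all genes, and 21.0% (bootstrap SE 0.504) over those above a log2 CPM of 3. That threshold cannot decide, since even an SD like that of the other libraries (0.28 to 0.32) would miss it. After the correction the SD of CEFFE 1 was 0.39, against 0.27 to 0.31 in the others, so more than the fitted trend set it apart. The difference of CEFFE 1 rose with GC, at rho 0.46 across genes, the value that prompted the test of GC as a part. With CEFFE 1 left out, control 1 had a rho of −0.29 against the other 2, control 2 0.07 and CEFFE 2 0.21. Such a trend was therefore not confined to CEFFE 1, and CEFFE 2 also rose with GC against the controls. Whether the trend in CEFFE 1 is technical stays open. The depth of CEFFE 1, at 26.8 M counts and within the 24.6 to 28.9 M of the others, argues against depth as the cause. A larger response to the extract in that library cannot be told apart from a technical difference, since the 2 CEFFE differences correlated across genes at rho 0.18 when libraries of the same number were paired and at 0.37 in the other pairing.

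Hypoxia and glycolysis genes were higher in CEFFE (median log2 fold change 0.32), though the directional fry test did not call the list (adjusted p = 0.36). The length and GC correction left a median of 0.24 and camera with the preset correlation past its threshold (adjusted p = 1.3e-17, in a range of 2.8e-27 to 1.69e-10 over 15 settings), which argues against that trend as the whole cause, though part of the median went with it, and without the correction the list had adjusted p = 0.922 with an estimated correlation. CEFFE 1 alone does not account for the shift, since 29 of 30 members stayed above 0 without it (median 0.22). That fit had no GC correction, and CEFFE 2 also rose with GC against the controls (rho 0.21). The list is rich in GC, with a median of 55.9% against 49.5% for all tested genes. A second list of 32 tested hypoxia-inducible genes, sharing none with the first, had a median of 0.18 (0.17 with 4 genes that had been dropped from it), at percentiles 98.56 to 100 of 10000 random lists in each CEFFE library against each control and 67.7 between the controls, although random lists leave out the correlation between genes of a list. A response of hypoxia-inducible genes may therefore be present, as a hypothesis; culture conditions that differed between groups, such as cell density or medium, were not tested, and a difference in poly-A selection between the groups (RN7SL2 at 1.24) stays open.

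Interferon-stimulated genes were lower in CEFFE (median −0.32), though the directional fry test did not call the list (adjusted p = 0.36). With the length and GC correction the median was −0.25, with camera at the preset correlation past its threshold (adjusted p = 4.43e-10, in a range of 4.62e-14 to 0.000233 over 15 settings), which argues against that trend as the whole cause, while without it the list had adjusted p = 0.922 with an estimated correlation. Without CEFFE 1 the median was −0.21 with 36 of 37 members below 0, and without control 2 it was −0.20. Neither of these fits had a GC correction, and CEFFE 2 rose with GC against the controls (rho 0.21). A second list of 45 interferon-inducible genes had a median of −0.15, with 30 below 0, at percentiles 0 to 3.91 of 10000 random lists in each CEFFE library against each control and 78.6 between the controls, with the same limit. Lower interferon-induced expression is a hypothesis that these values may fit, and a difference between the cultures other than the extract, or in poly-A selection (RN7SL2 at 1.24), stays open and untested.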
